A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

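Messenger RNA was sequenced from budding yeast (Saccharomyces cerevisiae) growing in log phase in YPD, a rich glucose medium. The 18 samples of the series are 12 samples of cells kept at 25 °C and 6 samples after a heat shock at 37 °C for 30 minutes. Each of the 4 strains kept at 25 °C gave 3 samples, which the series' design text describes as separate RNA isolations, so p-values measure the spread between isolations. Libraries were made with a poly(A)-selecting, strand-marking kit, per the labels' protocols. Whether the counting used strand, and what each aligner or counter was run with, is not given in the sources used here.

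The main table holds whole-number counts per gene, deposited by the authors without normalization, for 7130 genes in 12 libraries. A further table holds FPKM values (fragments scaled by gene length and depth) deposited by the authors for the same libraries. Per the submitters' processing notes, the tools were bcl2fastq 1.8.3, CASAVA, TopHat2 2.0.4, Picard 1.29, HTSeq 0.6.1 and Cufflinks 2.1.1, and the genome build was sacCer2. The role of each tool is not stated there. Gene names came from the deposited tables, and 6048 of the 7130 identifiers were found in the RefSeq gene table of assembly R64, which was used only for names, for which genes neighbour each other and for a search for copies of FES1. It is another build than the authors', so no coordinates are given.

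Columns were matched to samples by name. In 2 tables, 12 columns (6 in each) carry names that match no sample's label, and they were not used. The heat-shock samples were therefore not analysed here, and 4 of the 9 planned comparisons, those with heat-shocked cells, were not made. In the FPKM table, 3629 genes have 12 values, 1 for each column name, and in these each of the 12 columns correlated best with the counts of its own library across 2164 genes (r from 0.85 to 0.94). The other 3501 genes have 24 values for the 12 column names, only 3 columns matched their own library, and these genes were left out of every use of FPKM. Of the 2819 genes in the FPKM test, 6 are listed at 0 in a library that holds at least 100 counts of them, MFA1 among them (0 in 3 libraries).

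Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust fitting, TMM size factors, the default expression filter by group). All 12 libraries entered a single fit with strain as its only term, and p-values were adjusted by Benjamini-Hochberg over the 5719 genes that passed the filter. An adjusted p under 0.05 counted as a call. Where the text counts genes of a list that rose, fell, or were higher or lower, these are called genes. Levels are counts per library size (CPM, the usual depth-scaled unit), computed here with the TMM-scaled library sizes and are given as mean ± SD. The standard error (SE) of a log2 fold change was derived from the F statistic, and intervals are 95% intervals. Gene lists written before the data were examined were tested with camera (limma 3.58.1) on edgeR's log2 CPM with a preset correlation of 0.01, adjusted over the 22 lists with at least 5 tested genes. The remaining list, genes of the mitochondrial genome, could not be tested because all 28 such genes had 0 counts in every library.

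Genes named in the text followed a rule set before the data were examined. FES1 comes first. Each comparison then gives up to 8 genes with the largest and 8 with the smallest log2 fold change among called protein-coding genes that reach a mean of 10 CPM in 1 of the groups and whose replicates do not overlap. From each called list up to 4 genes with the smallest adjusted p follow, and all Hsf1 targets and SSA3, SSA4, HSP26, HSP12, SSE1, SSE2, RPN4, HAC1 and KAR2 may be named. Mating-type genes, auxotrophic markers and genes around FES1 are given as levels. TCM62 was placed in that last group in error, since it does not lie beside FES1. YBR099C and the genes of any count of 5 or fewer were chosen after their values were seen.

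The scripts were tested on simulated counts with the real means and library sizes. For fes1Δ against WT with 200 changed genes among 5684 tested, edgeR called 99% of 100 genes changed 2-fold and 87% of 100 genes changed 1.5-fold, with 8 false calls. In the same simulation, an unchanged group against WT gave 0 calls, and camera called the 1 changed list and none of the unchanged ones. Alternatives tried were RLE size factors, no expression filter, DESeq2 1.42.0, a fit of only the groups compared, a replicate block, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, each library left out in turn, and for lists an estimated correlation and fry. An edgeR result adjusted only over the genes of the FPKM test that passed the count filter was added after seeing the data. Total counts ran from 7608550 to 10246711 per library, so 3 counts correspond to between 0.293 and 0.394 CPM before TMM scaling. The TMM factors ran from 0.948 to 1.047, so 3 counts can lie slightly outside that range in the levels given here.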

Results

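The series profiles messenger RNA in yeast strains that differ at FES1, which encodes a nucleotide exchange factor of the Hsp70 chaperones and gives a short and a long splice isoform. The libraries are labelled WT, fes1Δ (the gene deleted), fes1ΔS and fes1ΔL (by the labels, lacking the S or the L isoform), with 3 libraries each. Total counts were 7994723 to 9321066 for WT, 7608550 to 8955839 for fes1Δ, 8415183 to 10246711 for fes1ΔS and 8999115 to 9700170 for fes1ΔL. All 12 replicate pairs differed by more than sampling noise (chi-square per degree of freedom from 2.64 to 15.09), so no pair was taken for a library deposited again, and each library was counted as 1 sample. The first principal component took 42.1% of the variance and the second 14.1%. On the first, the fes1ΔS libraries lay between 3.63 and 5.61, the WT and fes1ΔL libraries between -10.9 and -8.41, and those labelled fes1Δ above all others, up to 15.4.

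FES1 (YBR101C) did not follow the label of the deletion strain. Its level was 158 ± 7.49 CPM (SD, n = 3) in WT, 159 ± 8.59 CPM in the libraries labelled fes1Δ and 146 ± 3.27 CPM in fes1ΔL. In fes1ΔS it was 1434 ± 80.2 CPM. Against WT, the log2 fold change was 0.01 in the libraries labelled fes1Δ (95% interval -0.13 to 0.14), 3.18 in fes1ΔS (SE 0.07, adjusted p = 1.88e-17) and -0.11 in fes1ΔL (interval -0.25 to 0.02). Gene-level counts do not distinguish the isoforms or show which part of the gene the reads cover. URA3, an enzyme gene of uracil synthesis widely used as a selection marker, separated the libraries labelled fes1Δ from the rest. It had 1868, 1866 and 1590 counts in these and between 0 and 3 counts in each of the other 9 libraries. Because FES1 goes against the fes1Δ label, every direction given for that group below is that of the libraries so labelled. URA3 counts coincide with that label, so any effect of URA3 cannot be told apart from other differences of that group.

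**Figure D1:**
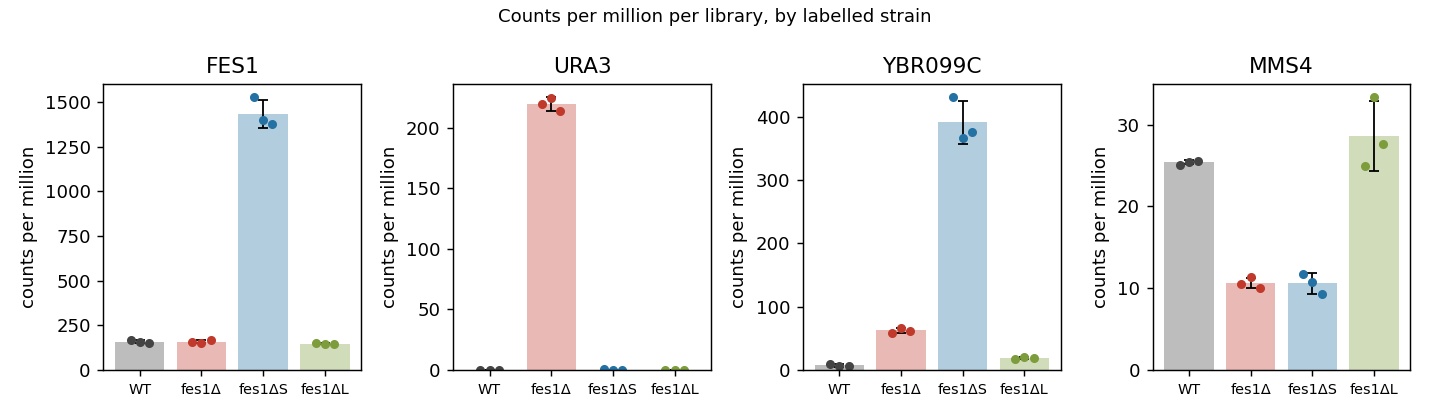
Levels (CPM) of FES1, URA3, YBR099C and MMS4 in each of the 12 libraries (points), with the mean (bar) and SD (error bar, n = 3) of each labelled strain; each vertical axis starts at 0 and has its own scale. FES1 is at 159 CPM in fes1Δ and 1434 CPM in fes1ΔS, and URA3 is seen in the fes1Δ libraries.

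By its labels, the comparison of fes1Δ with WT was set up for loss of both isoforms, although FES1 counts were at the WT level in these libraries. In the libraries labelled fes1Δ, Hsf1 target genes were higher and iron uptake genes lower. SSA4, a stress-inducible Hsp70, was 21.4-fold higher, at 1897 ± 198 CPM against 88.4 ± 3.91 CPM in WT (SD, n = 3, adjusted p = 6.22e-18). All 17 tested Hsf1 targets, the core heat shock factor regulon of chaperones, rose, with a median log2 fold change of 1.48. All 21 tested iron uptake genes had a negative log2 fold change, 20 of them called, with a median of -1.17. In all, 736 of 5719 genes were called, 327 higher and 409 lower, and 105 of them changed at least 2-fold.

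The Hsf1 targets ranged from a log2 fold change of 0.85 for HCH1 to 3.28 for BTN2, which encodes a protein-sorting chaperone. HSP104, the disaggregase, rose 5.50-fold (log2 2.46, SE 0.06, adjusted p = 2.92e-16), and the Hsp90 gene HSP82 rose by 2.26 on the log2 scale. HSP42 and HSP78, a small heat shock protein and a mitochondrial disaggregase, rose by 2.38 and 2.36. SSA1 rose by 2.19 and the Hsp40 genes YDJ1 and SIS1 by 1.05 and 1.48. Reads of the near-identical pairs SSA1 and SSA2, and HSP82 and HSC82 may have been divided between the copies, so their separate values are uncertain. For the related genes SSA3 and SSA4, an even division is argued against by their levels in the libraries labelled fes1Δ. SSA4 was at 1897 CPM there against 88.4 CPM in WT, and SSA3 at 62.7 CPM against 49.4 CPM. A small share of SSA4 reads counted as SSA3 is not excluded, so the value of SSA3 stays uncertain. Camera placed the list above other genes (adjusted p = 4.49e-42, and adjusted p = 0.0112 with an estimated correlation), and all 17 were also called when adjusted over the list alone. SSE1, an Hsp110 exchange factor, rose by 1.26 and its paralog SSE2 by 0.93. KAR2, the Hsp70 of the endoplasmic reticulum, rose by 0.89 and RPN4, the activator of proteasome genes, by 0.57, whereas HAC1 was at 0.05 (adjusted p = 0.619).

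**Figure D2:**
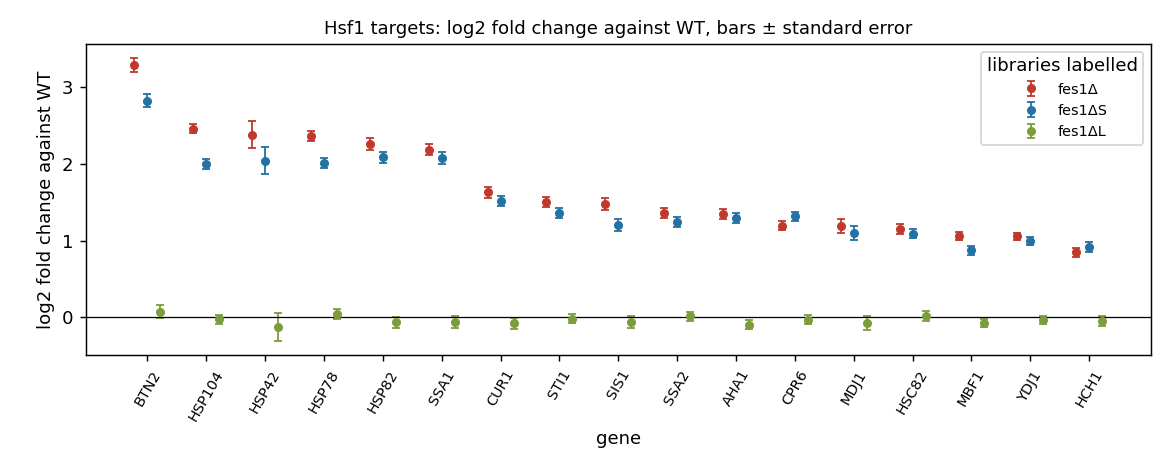
Log2 fold change against WT (vertical axis) of the 17 Hsf1 targets (horizontal axis), as points with SE bars, for the libraries labelled fes1Δ, fes1ΔS and fes1ΔL (n = 3 each). Values run from 0.85 to 3.28 in fes1Δ, from 0.87 to 2.82 in fes1ΔS and from -0.13 to 0.07 in fes1ΔL.

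Of the 21 iron uptake genes induced through Aft1, 20 were called lower, and also 20 when adjusted over the list alone. The multicopper ferroxidase FET3 had 488 ± 99.7 CPM against 1145 ± 49.7 CPM in WT (log2 -1.23, SE 0.12, adjusted p = 9.64e-06). The copper transporter CCC2 fell by 0.98, the permease FTR1 by 0.76 and the reductase FRE3 by 1.26. The mRNA-binding protein gene TIS11 fell by 1.85, and the siderophore genes FIT2, ARN2 and SIT1 by 1.62, 1.57 and 1.56. FIT2 was not called in a fit of only these 2 groups (adjusted p = 0.0823). FRE5, a reductase gene outside the list, fell by 2.06. Camera gave adjusted p = 1.70e-22 for the list and 0.0223 with an estimated correlation.

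The median log2 fold change of 46 general stress genes of the Msn2/Msn4 regulon was only 0.17, and 35 of them were not called. The other 11 were called higher and none lower (13 higher when adjusted over the list alone). The 11 included SSA4, the highest of the list at 4.42, the polyubiquitin gene UBI4 (1.09), SSE2 and the glycogen branching enzyme GLC3 (0.55). The small heat shock protein gene HSP26 rose by 1.87, but was not called in a fit of these 2 groups alone (1.87, adjusted p = 0.0759). HSP12 varied strongly between replicates, at 260 ± 57.6 CPM against 95.1 ± 68.7 CPM, and was not called (adjusted p = 0.198). Camera gave adjusted p = 3.47e-06 for this list and 0.593 with an estimated correlation. Of 16 mitochondrial chaperone and protease genes, 6 rose, among them SSC1 (0.77), HSP60 (0.64) and MDJ1 (1.19), and adjusted over the list alone 7 rose and 1 fell (adjusted p = 2.14e-04, and 0.0337 with an estimated correlation). HSP78 and MDJ1 are 2 genes that this list shares with the Hsf1 targets. In the list of 25 ubiquitin quality control genes, UBI4, shared with the Msn2/Msn4 list, and UBC4 (0.52) rose and the other 23 were not called (adjusted p = 0.00514, and 0.253 with an estimated correlation). Adjusted over the list alone, 2 rose. The ubiquitin list also shares HRD1 with the ER list, and the cell wall and pheromone lists share MSG5, 1 gene each.

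Among genes of mating, 9 of 19 pheromone response genes fell and 12 fell when adjusted over the list alone (adjusted p = 1.81e-07, and 0.129 with an estimated correlation). They included the agglutinin anchor AGA1 (-0.91), SST2 (-0.55), the kinase gene FUS3 (-0.52) and FAR1 (-0.51). Of genes expressed in MATa cells, given as levels without a list test, MFA1 had 46.1 ± 11.6 CPM against 94.9 ± 6.03 CPM in WT (log2 -1.05, adjusted p = 6.29e-04). Its FPKM is listed at 0 in fes1Δ replicates 1 and 3, which hold 289 and 425 counts of it, so the FPKM test (adjusted p = 0.153) does not bear on MFA1. The receptor gene STE2 had 440 ± 11.4 CPM against 658 ± 59.7 CPM (adjusted p = 4.43e-06), and the exporter gene STE6 274 ± 25.5 CPM against 318 ± 28.1 CPM without a call (adjusted p = 0.0645), though it was called lower without WT replicate 1 or fes1Δ replicate 1 (adjusted p = 0.0477 and 0.0222). STE3, the receptor gene of MATα cells, had 7.36 ± 3.12 CPM against 1.94 ± 0.18 CPM (adjusted p = 1.85e-04), while SAG1, another MATα gene, had 53.2 ± 3.66 CPM against 55.6 ± 7.05 CPM. Of 22 meiosis and sporulation genes, 4 rose and 1 fell, with 5 and 1 when adjusted over the list alone. The spore wall genes DIT1 (1.11) and DIT2 (1.33) and the recombination gene REC104 (0.81) were among those that rose, all from levels under 5 CPM, and on FPKM DIT2 and REC104 were not called (adjusted p = 0.0948 and 0.0523). The list had adjusted p = 5.62e-04, and 0.0337 with an estimated correlation.

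Ergosterol synthesis genes fell in 9 of 25 cases and in 14 when adjusted over the list alone, led by ERG27 (-0.31), ERG2 (-0.28), ERG28 (-0.43) and ERG24 (-0.26), and the list's adjusted p was 3.47e-06, or 0.0223 with an estimated correlation. Of 12 drug resistance genes induced through Pdr1 and Pdr3, 5 fell and 10 fell when adjusted over the list alone. PDR16 fell by 0.49, TPO1 by 0.47 and PDR15 by 0.86 (list adjusted p = 5.80e-06, and 0.253 with an estimated correlation). Of 20 Yap1 genes, 5 fell, among them the peroxidase genes GPX2 (-0.68) and TSA1 (-0.40), and adjusted over the list alone 2 rose and 9 fell (adjusted p = 0.00904, and 0.356 with an estimated correlation). The lists of ribosomal proteins, ribosome biogenesis, and TCA cycle and respiration were called upward with medians of 0.05, 0.10 and 0.12 (adjusted p = 0.0201, 8.93e-04 and 0.0197). Among 137 ribosomal protein genes, 3 rose and 6 fell (2 and 4 when adjusted over the list alone), so most called members went against the list. Among 82 ribosome biogenesis genes none was called either way, and among 49 TCA and respiration genes 8 rose and 4 fell (12 and 5 when adjusted over the list alone). Each had adjusted p = 0.809 with an estimated correlation and lost its call without at least 1 library. Ribosomal proteins lost it without WT replicate 3 or fes1Δ replicate 3 (adjusted p = 0.725 and 0.986). Ribosome biogenesis lost it without WT replicate 1 or fes1Δ replicate 1 (0.143 and 0.0867), and TCA and respiration without WT replicate 2 or fes1Δ replicate 3 (0.156 and 0.760). In the last list the lactate dehydrogenase gene CYB2 rose by 2.07 and the oxidase subunit COX5A by 0.33. The remaining lists were not called: proteasome and cell wall integrity (both adjusted p = 0.0790), glycolysis and phosphate (both 0.287), nascent chain chaperones (0.316), hexose transporters (0.845), and the ER unfolded protein response, Gcn4 and sulfur assimilation lists (each 0.952). The test pointed down in the last 3 lists, while the mean of the ER list (0.02) and the medians of the Gcn4 and sulfur lists (0.02 and 0.01) lay above 0.

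**Figure D3:**
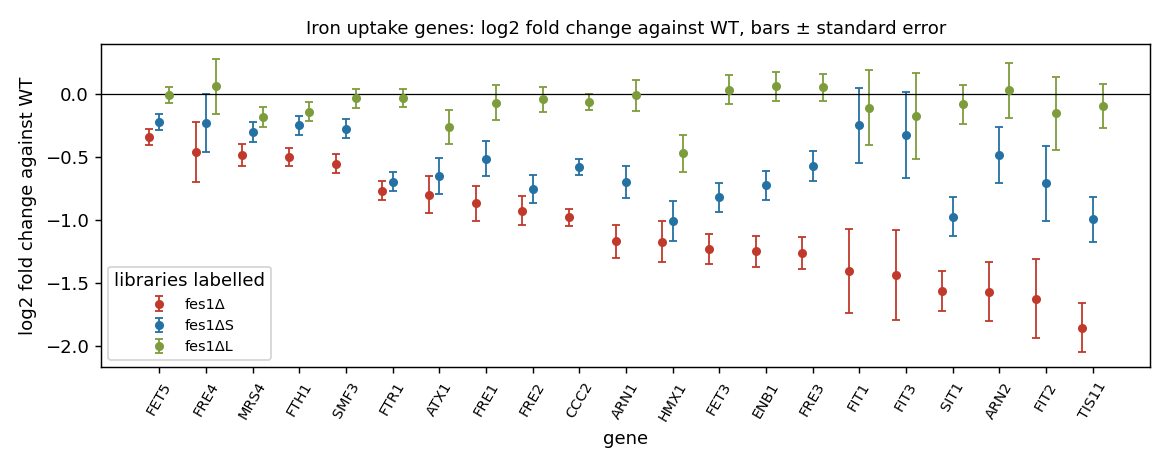
Log2 fold change against WT (vertical axis) of 21 iron uptake genes (horizontal axis), as points with SE bars, for the libraries labelled fes1Δ, fes1ΔS and fes1ΔL (n = 3 each). Values run from -1.85 to -0.34 in fes1Δ, up to -0.22 in fes1ΔS and from -0.47 to 0.06 in fes1ΔL.

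Other genes with large falls in the libraries labelled fes1Δ were IMD2, an enzyme of guanine nucleotide synthesis with close paralogs (-1.97), and GTO3 (-1.62). YJR005C-A fell by 1.86, but was not called without fes1Δ replicate 1 or 3 (-1.62 and -1.80, adjusted p = 0.118 and 0.0731) or in a fit of these 2 groups alone (-1.87, adjusted p = 0.178). YFL066C, a gene near a chromosome end with near-identical copies elsewhere and therefore uncertain, rose by 2.40. Without WT replicate 1 the count of calls fell from 736 to 486, and a fit of only these 2 groups gave 466. Tested on the deposited FPKM values, 76 of 2819 genes were higher and 361 lower, against 146 and 189 by counts over the 2682 of them that passed the count filter.

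By its labels, the comparison of fes1ΔS with WT was set up for loss of the S isoform, and total FES1 was 9.08-fold higher in these libraries than in WT. The Hsf1 targets were again higher, all 17 of them, also when adjusted over the list alone, with a median log2 fold change of 1.31 (adjusted p = 1.22e-49, and 0.00638 with an estimated correlation). SSA4 had 951 ± 59.5 CPM against 88.4 ± 3.91 CPM in WT (log2 3.43, SE 0.08, adjusted p = 1.42e-16). BTN2 rose by 2.82, HSP82 by 2.09, SSA1 by 2.07, HSP42 by 2.04, HSP78 by 2.01 and HSP104 by 2.00. SSE1 rose by 1.23, SSE2 by 1.61, KAR2 by 0.85 and RPN4 by 0.67. In all 381 genes were called, 184 higher and 197 lower, and 50 changed at least 2-fold.

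Iron uptake genes fell in 15 of 21 cases in fes1ΔS and in 16 when adjusted over the list alone, with a median of -0.57. FTR1 fell by 0.69, CCC2 by 0.57, FRE2 by 0.75 and the heme oxygenase gene HMX1 by 1.00 (list adjusted p = 1.66e-14, and 0.0753 with an estimated correlation). Of 46 Msn2/Msn4 genes, 13 rose, among them UBI4 (0.83) and SSA3 (0.48), and 19 rose when adjusted over the list alone (adjusted p = 7.42e-07, and 0.526 with an estimated correlation). The median of this list was 0.14, and 33 genes were not called. Mitochondrial chaperones rose in 5 of 16 cases, with HSP60 at 0.90, SSC1 at 0.72 and MDJ1 at 1.10 (adjusted p = 2.59e-05, and 0.0333 with an estimated correlation), and adjusted over the list alone 7 rose and 1 fell. The ubiquitin list had 3 genes higher, UBC4 at 0.57 among them, and 5 when adjusted over the list alone (adjusted p = 5.14e-04, and 0.217 with an estimated correlation). Phosphate genes fell in 4 of 16 cases and in 6 when adjusted over the list alone, with VTC1 at -0.41, the phosphatase gene PHO11 at -0.93 and the transporter gene PHO89 at -1.26 (adjusted p = 1.03e-05, and 0.232 with an estimated correlation). Against fes1ΔL, 0 of the 16 were called in fes1ΔS, and the list was not called (camera adjusted p = 0.133). PHO11 and PHO12 are near-identical, so the value of each is uncertain.

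Pheromone genes fell in 6 of 19 cases and in 10 when adjusted over the list alone, AGA1 by 0.69 (adjusted p = 4.07e-05, and 0.232 with an estimated correlation). STE2 had 509 ± 22.2 CPM and MFA1 51.4 ± 0.87 CPM, both called below WT by counts, and STE3 had 2.21 ± 0.11 CPM. Yap1 genes fell in 5 of 20 cases and in 8 when adjusted over the list alone, GPX2 by 0.61 and ATR1 by 0.45 (adjusted p = 1.44e-04, and 0.217 with an estimated correlation). The proteasome list was called upward with a median of 0.05 although RPN4 was its only called gene, also when adjusted over the list alone (adjusted p = 0.01, and 0.563 with an estimated correlation). The call ended without WT replicate 2 or fes1ΔS replicate 1 (adjusted p = 0.147 and 0.0791). The ergosterol list had 2 genes lower, also when adjusted over the list alone (adjusted p = 0.0409, and 0.232 with an estimated correlation). Without WT replicate 2 or 3, or fes1ΔS replicate 2 or 3, it was not called (0.0594, 0.0735, 0.0818 and 0.105). IMD2 fell by 2.04, FRE5 by 1.37, MMS4 by 1.25, CIN2 by 1.21, YLR460C by 1.07 and GTO3 by 1.07. Without fes1ΔS replicate 2 the count of calls was 251, and the FPKM test gave 58 of 2819 genes higher and 153 lower, against 94 and 102 by counts over the 2682 of them that passed the count filter.

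By its labels, the comparison of fes1ΔL with WT was set up for loss of the L isoform. Only 4 of 5719 genes were called by edgeR, with 232 at an unadjusted p under 0.05 and 5 called by DESeq2. The 4 genes were YBL113C (1.61, adjusted p = 6.96e-07), YBR099C (1.42, adjusted p = 6.40e-05), PHO89 (-1.33, adjusted p = 0.00653) and YLR466C-B (-3.17, adjusted p = 6.96e-07). YBL113C and YLR466C-B lie near chromosome ends in repeated sequence and are uncertain. PHO89 was not called without WT replicate 2 (adjusted p = 0.0599), fes1ΔL replicate 2 (0.0536) or fes1ΔL replicate 3 (0.0683). On FPKM, neither YBR099C (1.17, adjusted p = 0.979) nor PHO89 (-0.95, adjusted p = 0.379) was called. None of the 17 Hsf1 targets was called, also when adjusted over the list alone, and their log2 fold changes lay between -0.13 and 0.07. The interval was -0.26 to 0.08 for SSA4 and -0.15 to 0.10 for HSP104.

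In fes1ΔL, 1 of 16 phosphate genes fell and 5 fell when adjusted over the list alone (adjusted p = 5.20e-08, and 0.851 with an estimated correlation). The transporter gene PHO84 had 48.1 ± 0.97 CPM against 141 ± 13.8 CPM in WT and was not called (log2 -1.55, interval -3.29 to 0.18, adjusted p = 0.984), whereas a fit of only these 2 groups called it (adjusted p = 4.15e-08). The fit of all 12 libraries includes fes1Δ replicate 1, where PHO84 was at 295 CPM against 42.9 and 34.9 CPM in the other fes1Δ libraries. Of the other lists called by camera, none had a called gene, and each had adjusted p = 0.912 with an estimated correlation. These were proteasome (median -0.06), ribosome biogenesis (0.04), Yap1 (-0.08) and TCA and respiration (-0.05), and each lost its call without at least 1 library (full-set adjusted p = 5.54e-04, 0.0255, 0.0374 and 0.0242). The adjusted p was 0.291 without WT replicate 1 for proteasome, Yap1 and TCA and respiration. For ribosome biogenesis it was 0.611 without WT replicate 1, where the direction turned downward, 0.826 without WT replicate 3, and 0.594 and 0.116 without fes1ΔL replicates 2 and 3. For Yap1 it was 0.181 without WT replicate 3 and 0.486 without fes1ΔL replicate 2, and for TCA and respiration 0.594 and 0.210 without fes1ΔL replicates 2 and 3. A fit of only these 2 groups called 10 genes.

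The direct comparison of fes1Δ with fes1ΔS sets strains labelled as lacking both isoforms and the S isoform against each other, and FES1 and URA3 counts differ between them as given above. SSA4 was higher in the libraries labelled fes1Δ by 1.00 on the log2 scale (SE 0.07, adjusted p = 3.80e-08), and HSP104, BTN2 and HSP78 were higher by 0.46, 0.46 and 0.35. These 3 were the Hsf1 targets called, with 5 of 17 when adjusted over the list alone (list adjusted p = 1.42e-05, and 0.406 with an estimated correlation). SSE2 went the other way, at 116 ± 8.15 CPM against 185 ± 10.1 CPM in fes1ΔS (log2 -0.68, adjusted p = 0.00387). Iron genes were lower in fes1Δ than in fes1ΔS for 3 of 21, and for 14 when adjusted over the list alone, with CCC2 at -0.40 and FRE3 at -0.69 (list adjusted p = 1.54e-13, and 0.127 with an estimated correlation). In all 141 genes were called, 70 higher and 71 lower.

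Besides URA3, PRM8 (1.67), the sporulation gene YSW1 (1.23) and YLR112W (0.70) were higher in the libraries labelled fes1Δ than in fes1ΔS. SCP1 (-1.39), the arginine synthesis genes ARG1 (-1.03) and ARG7 (-0.77) and BIG1 (-0.82) were lower. Phosphate genes were higher for 4 of 16, PHO89 by 1.28, also when adjusted over the list alone (list adjusted p = 2.89e-05, and 0.406 with an estimated correlation), though the list was not called without fes1Δ replicate 1 (0.128). The glycolysis list was lower (adjusted p = 5.44e-04, and 0.486 with an estimated correlation), with 2 of 17 genes called, HXK2 (-0.32) and TDH2 (-0.45), and 5 when adjusted over the list alone. Camera also placed the ergosterol, drug resistance, pheromone and Gcn4 lists lower (adjusted p = 2.89e-05, 2.96e-05, 0.00151 and 0.00797, and 0.0885, 0.406, 0.486 and 0.558 with an estimated correlation). It placed the meiosis, ribosome biogenesis, TCA and respiration, and ribosomal protein lists higher (0.00759, 1.66e-04, 0.00155 and 0.0309, and 0.174, 0.703, 0.70 and 0.832 with an estimated correlation). Called genes were 2 lower for ergosterol (5 when adjusted over the list alone), 0 for drug resistance (7 lower), 3 lower for pheromone (5), 2 lower for Gcn4 (2), 2 higher for meiosis (4 higher and 1 lower) and 2 lower for ribosomal proteins (1), the last against the direction of the list. In ribosome biogenesis and in TCA and respiration none was called either way. Of these lists, pheromone and ribosome biogenesis were not called without fes1Δ replicate 1 (0.0517 and 0.259), ribosome biogenesis without fes1ΔS replicate 1 (0.129), and Gcn4 and TCA and respiration without fes1Δ replicate 3 (0.376 and 0.857). The ribosomal protein list was not called and turned downward without fes1Δ replicate 3 or fes1ΔS replicate 1 (0.775 and 0.721). With no expression filter this list was not called either (0.0659). Without fes1ΔS replicate 1, 2 or 3 the count of calls was 59, 90 or 73.

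The comparison of fes1ΔS with fes1ΔL sets the isoform strains against each other. All 17 Hsf1 targets were higher in fes1ΔS, also when adjusted over the list alone, with a median of 1.38 (adjusted p = 1.14e-59, and 0.00334 with an estimated correlation). SSA4 had 951 ± 59.5 CPM against 83.0 ± 6.21 CPM in fes1ΔL. RPN4 was higher by 0.79, UBC4 by 0.70, and the branched amino acid genes ILV2 and LEU4 by 0.58 and 0.41. IMD2 (-2.15), MMS4 (-1.43), CIN2 (-1.14), FET3 (-0.85) and the transporter gene VMR1 (-0.91) were lower. Of 21 iron genes 9 were lower, and 14 when adjusted over the list alone (adjusted p = 3.59e-14, and 0.0799 with an estimated correlation). Of 16 mitochondrial chaperone genes 5 were higher, and 6 when adjusted over the list alone (adjusted p = 1.49e-07, and 0.0101 with an estimated correlation). Camera also placed the Msn2/Msn4, proteasome and ubiquitin lists higher (adjusted p = 6.24e-09, 1.48e-07 and 6.65e-05, and 0.405, 0.317 and 0.132 with an estimated correlation), with 13, 1 and 3 genes higher and 14, 1 and 6 when adjusted over the list alone. The pheromone and Yap1 lists were lower (3.16e-05 and 0.00811, and 0.286 and 0.317 with an estimated correlation), with 4 and 3 genes lower, and 9 and 5 when adjusted over the list alone, where 2 Yap1 genes were also higher. The nascent chain chaperone, cell wall and Gcn4 lists were higher (adjusted p = 0.0246, 0.0414 and 0.0215), with 1, 2 and 4 genes higher and 2 Gcn4 genes lower (1, 3 and 5 higher and 2 lower when adjusted over the list alone). The drug resistance list was lower (0.0162), with 1 gene lower and 2 when adjusted over the list alone. Each of these 4 lists had an adjusted p above 0.05 without at least 1 library, for example 0.0778, 0.0763 and 0.0879 without fes1ΔS replicate 3 for the nascent chain, cell wall and drug resistance lists and 0.0551 without fes1ΔL replicate 2 for Gcn4. With an estimated correlation the 4 lists had adjusted p = 0.286, 0.317, 0.466 and 0.489. In all 276 genes were called, 158 higher and 118 lower, and a fit of only these 2 groups called 464. On FPKM the balance turned, with 57 of 2819 genes higher and 129 lower, against 78 and 56 by counts over the 2682 of them that passed the count filter. The FPKM values were not rescaled between libraries, and the median of all genes there was -0.08.

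Fold changes of the libraries labelled fes1Δ and of fes1ΔS, both against WT, correlated across 5719 genes with Pearson r = 0.681, where genes are not independent replicates. For comparison, counts of all 12 libraries, WT included, were drawn gene by gene from the WT means, with no strain changed. They gave a mean r of 0.501 over 30 draws and at most 0.565. The covariance was 0.0655 against a simulated 0.00885, a difference of 0.0566. Of the calls, 145 genes were higher in both and 134 lower in both, where independent lists would share 10.5 and 14.1, and 0 went in opposite directions. The simulated unchanged groups shared 0 calls. With no strain changed, few calls could arise at all, so this does not measure the overlap that comes from shared controls. The 3 WT libraries cannot be divided into parts of at least 2, so part of the excess over independent lists may come from the shared controls. The simulated covariance gives that part only for redrawn WT libraries with independent genes. The part played by the 3 real WT libraries was not measured. Over all comparisons, 9 of 52 camera calls held with an estimated correlation: Hsf1 targets and mitochondrial chaperones in the comparisons of fes1Δ and fes1ΔS with WT and of fes1ΔS with fes1ΔL, and the iron, ergosterol and meiosis lists in fes1Δ against WT.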

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

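The edgeR result over genes of the FPKM test was chosen after seeing the data; the other alternatives were planned. Counts of called genes stayed within 1.5 times of the main count with RLE size factors, no filter, DESeq2 and the replicate block in all 5 comparisons. A fit of only the groups compared gave 466 (fes1Δ against WT), 10 (fes1ΔL against WT) and 464 (fes1ΔS against fes1ΔL), from fewer samples. The FPKM test called 437, 211, 2 and 41 genes for fes1Δ, fes1ΔS and fes1ΔL against WT and fes1Δ against fes1ΔS, and edgeR over the 2682 of those 2819 genes that passed the count filter called 335, 196, 3 and 62, with 134 for fes1ΔS against fes1ΔL, from fewer genes. The share of higher calls in the FPKM test was 17.4% for fes1Δ and 27.5% for fes1ΔS against WT, 39.0% for fes1Δ against fes1ΔS and 30.6% for fes1ΔS against fes1ΔL. The FPKM values were not rescaled between libraries for this test. The median of all genes there lay between -0.08 and 0.01, against between -0.0029 and 0.0017 by counts over the 2682 genes. A median below 0 moves the balance of calls towards lower genes, and how much of the balance it accounts for was not tested. On FPKM, 2 genes were higher and 0 lower for fes1ΔL.

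Leaving out each library in turn gave 486 to 1051 calls for fes1Δ against WT, 251 to 410 for fes1ΔS, 3 to 5 for fes1ΔL, 59 to 128 for fes1Δ against fes1ΔS and 185 to 221 for fes1ΔS against fes1ΔL. The correlation of the fes1Δ and fes1ΔS effects lay between 0.637 and 0.708 in those fits and was 0.719 over genes with a mean count of at least 100. Camera called 52 lists over the 5 comparisons, 46 to 57 without a library, 35 by fry and 9 with an estimated correlation. The direction of a called list turned, without a call, for ribosome biogenesis in fes1ΔL against WT without WT replicate 1 (adjusted p = 0.611, range over libraries left out 5.02e-14 to 0.826). It also turned for ribosomal proteins in fes1Δ against fes1ΔS without fes1Δ replicate 3 or fes1ΔS replicate 1 (0.775 and 0.721, range 3.40e-05 to 0.775), and the cause was not tested. Of 250 called results for named genes, 190 kept their call in every alternative that gave a value, 60 lost it in at least 1, and 0 changed direction. Many of these genes were chosen for large changes or small adjusted p in the same libraries. The kept share may therefore not hold for other called genes.

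For libraries of different strains with the same replicate number, the correlation of their deviations ran from -0.19 to 0.29 over 18 pairs, 4 of them above 0.1. The 36 other pairs ran from -0.26 to 0.24, and 6 of 12 libraries correlated best with their own number. Between WT and fes1ΔL the same-number pairs were all positive (0.289, 0.213 and 0.0960). Their other pairs ran from -0.261 to 0.0975, so a likeness by replicate number is not excluded for these 2 strains. With the replicate block, 717, 402, 5, 138 and 274 genes were called in the 5 comparisons, and 53 lists. The planned heat-shock comparisons and their alternatives were not run. With totals of 7608550 to 10246711 counts, 3 counts are 0.293 to 0.394 CPM before TMM scaling, depending on the library. Levels in or below that range rest on only a few counts.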

Other observations

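The tests in this part of FES1, YBR099C and the neighbours of Hsf1 targets were chosen after the values of these genes were seen, and the expected outcomes of the label swap, kept part, read-through and splits tests were written down after their results were seen. Genes beside FES1, YBR099C and MMS4, also differed between strains. YBR099C, a reading frame outside the RefSeq table, had 6.96 ± 1.84 CPM (SD, n = 3) in WT, 62.4 ± 4.26 CPM in the libraries labelled fes1Δ, and 18.8 ± 2.03 CPM in fes1ΔL. In fes1ΔS it was higher than in WT by 5.80 on the log2 scale (SE 0.12, adjusted p = 1.42e-16). MMS4, a DNA repair nuclease gene, had 25.4 ± 0.24 CPM in WT, 10.6 ± 0.64 CPM in fes1Δ, 10.6 ± 1.28 CPM in fes1ΔS and 28.6 ± 4.28 CPM in fes1ΔL. EXO84, on the other side of FES1, was not called against WT by counts over all libraries, but was called lower in fes1Δ without fes1Δ replicate 1 (adjusted p = 0.0316) and in fes1Δ and fes1ΔS on FPKM (0.00543 and 0.00879). It had 59.7 ± 2.19 CPM in WT, 52.7 ± 3.15 CPM in fes1Δ, 51.9 ± 1.79 CPM in fes1ΔS and 62.4 ± 0.58 CPM in fes1ΔL. By counts it was called lower in fes1ΔS than in fes1ΔL (log2 -0.27, adjusted p = 0.0130), though the call was lost without fes1ΔL replicate 2 or fes1ΔS replicate 2 (-0.26 and -0.24, adjusted p = 0.0524 and 0.0763). The chromosome medians of the log2 fold change against WT lay within 0.0323 of 0 in all 3 strains.

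FES1 was counted at WT level in the libraries labelled fes1Δ. If the deletion removes the counted part, a swap of labels among the 12 libraries would leave at least 1 with next to no FES1. The lowest level was 144 CPM, which argues against a swap under that condition only. If part of the gene is kept and counted, the lowest level does not decide about a swap. In assembly R64, 0 further places matched the FES1 reading frame over at least 50 bases at 90% identity. This argues against reads from a near-identical copy within that reference genome. A copy absent from R64 would not be seen by this search and is not excluded. Part of the gene may be kept and still counted in this strain, at a ratio of 0.111 to the level in fes1ΔS. Gene-level counts do not show which part the reads cover, so this stays open, as does a wrong label shared by all 3 libraries, which alone hold URA3 counts of 1590 to 1868 and have the largest rise of SSA4 (4.42 against 3.43 in fes1ΔS).

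YBR099C was higher and MMS4 lower beside the altered gene. A general rise of frames outside the RefSeq table is argued against by the median log2 fold change of the 107 other such frames in fes1ΔS, -0.12. Transcription may run on past the end of FES1 in the altered strains; YBR099C was also higher in fes1ΔL by counts, by 1.42, though not called on FPKM (adjusted p = 0.979), and FES1 was not. Counts per gene do not show whether reads run on without a gap, and overlapping or antisense frames are uncertain because the use of strand is not stated, so this stays open.

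CIN2, beside HSP82, and VPS62, beside BTN2, fell by 1.25 and 0.91 in the libraries labelled fes1Δ. A fall general to neighbours of Hsf1 targets was a candidate explanation, but the median of the 29 other tested neighbours was 0.0295, with 2 called lower and 5 higher. LST8, beside SIS1, was among the latter at 1.19. Low counts are argued against as well, since the mean expression of the pair lay at percentile 24.8 of tested genes. No other explanation was tested.

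Each comparison sets 3 libraries against 3, and the 10 splits are too few for a share under 0.05. The real split called 736, 381, 141 and 276 genes for fes1Δ and fes1ΔS against WT, fes1Δ against fes1ΔS and fes1ΔS against fes1ΔL, and the highest other split 0 in each, so that 1 of 10 splits, the real one, reached the real count. Every other split mixes the 2 strains, so a difference between them becomes spread within its groups, whatever its cause. The lack of calls in the other splits therefore does not decide whether the real difference arose by chance. For fes1ΔL against WT the real split called 4 genes and the highest other 33, and 2 of 10 splits, the real one included, reached the real count. That other split set WT replicates 1 and 3 with fes1ΔL replicate 1 against the rest, which points to a structure of the samples, and what it is was not tested.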
